A study of Danio rerio with 23 samples.

How the data were processed

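The series measured RNA of zebrafish embryos on 23 printed arrays of long oligonucleotides from 3 sets, with 2 labelled samples per array. Per the labels, RNA of the mesendoderm and sorting experiments was amplified from 0.5 to 1.0 µg, and 10 to 15 µg of total RNA was labelled without amplification for the FoxH1 experiment. Per the labels, each comparison of sorted cells was repeated with the dyes exchanged, on 4 arrays of each orientation for mesendoderm and 3 for each control, and the FoxH1 experiment had 2 arrays of 1 orientation and 1 of the other. The mesendoderm arrays came from more than 1 strain, and the labels do not tie a strain to an array.

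The deposited scanner files give, per the file headers, the intensity of each spot in 2 channels as summed and mean brightness with the mean and SD of the local background. The mean intensity deposited was already less the local background. The deposited files also give a calibrated ratio, which in the values equalled the ratio of the channel means divided by 1 constant per array, a quality fraction from 0 to 1 per ratio, and the spot area in pixels. The table of deposited values held the log2 of that calibrated ratio in 100% of spots, with array medians between -0.104 and 0.132. The image software and scanner are not given in the sources used here. Spots not found made up 4.77% to 10.54% per array. The file of replicate 6 of green cells against whole embryos held 22147 of 36288 spots.

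Intensities with background were recovered from the summed brightness and the area. Background was corrected with normexp (offset 50) and ratios were normalized by loess within arrays (span 0.3, 4 iterations) in limma 3.58.1 with statmod 1.5.0, R 4.3.3 and the package data.table, version 1.17.8. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The planned median background was not in the files, and the mean was used. Control, empty or unnamed spots, 2134 in all, were left out of the tests, and 33803 probes remained. A probe was tested if present on all arrays or all but 1 (on all 3 in the FoxH1 comparison) and above background by 2 SDs of the background in at least 1 channel, a rule that removed no tested probe.

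Ratios were kept in the sample order of the files, which was taken as the same on every array of a comparison. Those of the FoxH1 comparison were inverted on all arrays to give FoxH1 over control. The dyes in the labels served to pair arrays and to set the dye term. For the sorted cells, a forward array and its swap were averaged and tested by limma with moderated t statistics. Since the labels do not pair them, every pairing was fitted (24 for mesendoderm and 6 for each control), and the largest adjusted p and SE over pairings are given. Where a probe was missing on 1 array, the array paired with it counted in the ratio but not in the SE or p. The FoxH1 fit had a term for the dye. P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and they measure the spread between these arrays. The controls came from 1 strain, so the spread between strains enters only the mesendoderm comparison.

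The direction was checked by the local background, which was higher in the channel labelled Cy3 on all arrays but those of red against green cells, where it was so on 0 of 6. The basis of this check was set before marker genes were looked at, and markers were then viewed under both directions.

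Gene symbols came from 4 sources: EST clone names (1534 probes), RefSeq accessions (1313), probe titles (815) and the symbol column (197), which named 3859 probes of 2509 genes, and 29944 probes had no symbol. After results were seen, 4 source plates were found to give nearly the same ratios well by well in the mesendoderm comparison (r between 0.973 and 0.99), with lower r in green cells (0.939 to 0.968) and red cells (0.45 to 0.67), and another plate shared them in part (r at most 0.456), against at most 0.178 for all remaining plates. Of these 5 plates, 1 kept its gene names, since its ratios correlated at 0.82 with those of other probes of the same genes. The names of the other 4, on 183 of 1520 probes, were withheld. The limit on r of 0.3 over at least 100 wells was chosen after the results were seen, and with all names kept the lists that passed numbered 4, 2, 0 and 7 in the mesendoderm, green cell, red cell and FoxH1 comparisons.

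Each gene was represented by its probe of the highest mean brightness. Named genes were, per comparison, the 10 with the largest increase and the 10 with the largest decrease among genes that passed with the same sign on every array, up to 4 passing members of each list with the largest ratio (or 2 where none passed), and foxh1. Some genes that this rule names are not reported here, and they were left out of the search for arrays far from the others, while the lists and counts include them. There were 20 lists of at least 5 measured genes: margin and mesendoderm, endoderm, dorsal organizer, FGF feedback, Wnt responsive, ventral BMP, neurectoderm, non-neural ectoderm, enveloping layer, yolk syncytial layer, germ plasm, immediate early, heat shock and chaperone, p53 target, cell cycle, retinoic acid, Nodal pathway, adhesion and gastrulation movement, ribosomal protein and proteasome genes. Lists were tested by limma's camera with a preset correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists. Lists, tests, the rule for named genes and most alternatives were set before the data were examined. Overlaps were tested by Fisher's exact test with probes as units, which are not independent. For the controls that both held green cell RNA, chance came from 20 simulations of unchanged groups with that RNA taken as shared.

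The method was tested on simulated data with 200 changed probes. Changes of 0.5, 1 and 2 on the log2 scale were found at 25.4%, 74.6% and 97% in the mesendoderm design, with 9 unchanged probes called. The shares were 0%, 17.9% and 48.5% for green cells, 7.5%, 53.7% and 87.9% for red against green cells, and 0% at every size for FoxH1. Few of the 31493 to 32687 simulated probes changed, so the adjusted p was harder to pass than where many probes change. These shares may therefore be too low for such data. In the green cell data, 396 of 399 probes at least 2-fold higher and 1264 of 1267 at least 2-fold lower passed.

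Alternatives covered the thresholds, background correction, normalization, the brightness filter, spot quality, the deposited log2 ratios, the pairing of dye swaps, the dye term, the list test, the probe per gene and each array left out in turn. Spot flags had only 1 value, so spots of quality 0 were left out in their place.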

Results

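Gene expression in zebrafish embryos was measured on 23 printed oligonucleotide arrays, each of which carried 2 RNA samples labelled with different dyes. Of these, 8 arrays set mesendoderm precursors (the cells that give rise to mesoderm and endoderm) against neurectoderm precursors (which give rise to the nervous system). A further 6 arrays set sorted cells with unconverted Kaede against whole embryos, and 6 set sorted cells with photoconverted Kaede against sorted cells with unconverted Kaede. Kaede is a green fluorescent protein that turns red under ultraviolet or violet light, so these cells are called green and red here. The last 3 arrays set embryos injected with a FoxH1 morpholino, an antisense oligonucleotide, against embryos injected with a control morpholino. Embryos of the sorting and morpholino experiments were at 40% epiboly, shortly before gastrulation. Each array held 36288 spots, and between 83.5% and 97.7% of the spots on an array lay above background in each channel. Median background-subtracted brightness was between 405 and 1437 in the mesendoderm comparison and between 155 and 499 in the FoxH1 comparison. The small number of arrays limits the precision of every value.

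Among genes with a symbol, those most enriched in mesendoderm over neurectoderm precursors included mesodermal and endodermal regulators. The ephrin ligand gene efnb2b was higher by 4.14 ± 0.17 on the log2 scale (SE, n = 8 arrays in 4 dye-swap pairs, limma adjusted p = 8.88e-05), and the LIM homeobox gene lhx1a by 4.08 ± 0.20 (adjusted p = 0.000172). The endoderm regulator sox32 was higher by 3.82 ± 0.12, and gata5 and gata6, zinc finger genes of endoderm and heart, by 3.32 ± 0.09 and 3.25 ± 0.12. In the other direction, lhx5, a LIM homeobox gene of the anterior neural plate, had a ratio of -2.58 ± 0.20 (adjusted p = 0.000698). The Hairy-related genes her3, her4.1 and her4.5 followed at -2.0 ± 0.35, -1.59 ± 0.20 and -1.49 ± 0.17.

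Among the other genes with the largest increases were flrt3 (log2 ratio 3.75), which encodes a membrane protein of FGF signalling, the retinol dehydrogenase gene rdh10a (3.73), the T-box gene tbr1b (3.49), the signalling factor gene fgf3 (3.49) and the protocadherin gene pcdh8 (3.36). By the rule that named them, each had the same sign on all 8 arrays, and so did the largest decreases. Those were completed by prdm14 (-1.46), rpe65b (-1.37), the anterior neural homeobox gene hesx1 (-1.33), msx1a (-1.32), the guanylate cyclase gene gucy2d (-1.23) and the germ cell gene nanos3 (-1.15). For msx1a the other 2 of its 3 probes lay in the opposite direction, at 0.32 (adjusted p = 0.0135) and 0.26 (adjusted p = 0.0586), so its decrease rests on 1 probe.

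**Figure D1:**
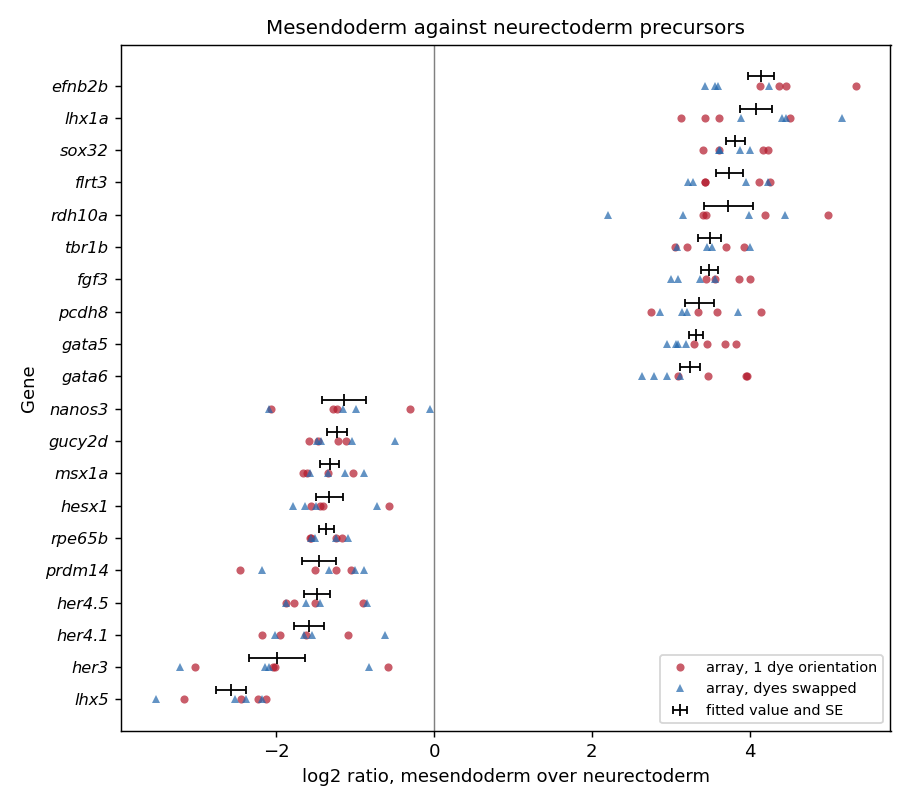
Log2 ratio of mesendoderm over neurectoderm precursors (horizontal axis) for the 10 named genes with the largest increases and the 10 with the largest decreases (vertical axis). Circles and triangles are single arrays of opposite dye orientation, n = 8 per gene, and black bars are the fitted value with its SE. The increases reached 4.14 for efnb2b and the decreases -2.58 for lhx5.

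Margin and mesendoderm genes rose as a group. Of 28 measured members, 23 were higher, 1 was lower and 4 did not pass the test, with the same counts adjusted over the list alone, and the median log2 ratio was 2.19. Besides efnb2b, lhx1a and sox32, fgf3 stood out at 3.49 ± 0.11. In limma's camera test with a preset correlation the list had an adjusted p = 6.14e-05, against an adjusted p = 0.617 with an estimated correlation. Dorsal organizer genes rose too: 17 of 24 were higher, none was lower and 7 did not pass, again with the same counts adjusted over the list alone. Their median was 1.67, with gsc, the classical organizer homeobox gene, at 3.04 ± 0.26 and foxa3 at 2.89 ± 0.13 (camera adjusted p = 0.00119; adjusted p = 0.617 with an estimated correlation). Wnt responsive genes rose, with 10 of 12 higher, 1 lower and 1 not passing, the same adjusted over the list alone, and a median of 1.21. Among them sp5a reached 3.21 ± 0.09, the Wnt antagonist gene dkk1b 2.56 ± 0.11, wnt8a 2.26 ± 0.18 and axin2 2.05 ± 0.18 (camera adjusted p = 0.0197; adjusted p = 0.617 with an estimated correlation).

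Proteasome genes fell as a group, with 1 of 13 higher, 8 lower and 4 not passing, the same adjusted over the list alone, and a median of -0.40. The subunit genes psmb5, psma6l and psmb6 were at -0.59 ± 0.12, -0.57 ± 0.17 and -0.49 ± 0.13, while psmd11b rose to 0.93 ± 0.21 (camera adjusted p = 0.0197; adjusted p = 0.617 with an estimated correlation).

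The endoderm list had the highest median, 2.59, with 8 of 11 members higher, 2 lower and 1 not passing, yet as a list it missed the threshold (camera adjusted p = 0.0618). The same held for FGF feedback genes, where 5 of 8 were higher and 1 lower, or 6 higher and 2 lower adjusted over the list alone, with fgf8a at 2.76 ± 0.08 and spry4, a feedback inhibitor, at 2.07 ± 0.20 (adjusted p = 0.118). Of 15 Nodal pathway components, 10 were higher and 3 lower, or 4 lower adjusted over the list alone. The Nodal antagonist genes lft1 and lft2 were at 2.99 ± 0.08 and 2.80 ± 0.21, and mixl1 was at 2.59 ± 0.13 (list adjusted p = 0.153). Of 11 retinoic acid genes, 6 were higher and none lower, among them aldh1a2, which encodes a retinoic acid synthesising enzyme, at 2.99 ± 0.14 (list adjusted p = 0.173). The neurectoderm list went both ways, with 13 of 36 members higher, 8 lower and 15 not passing (list adjusted p = 1). In it, six3b and nr2f1a were higher by 2.18 ± 0.10 and 1.93 ± 0.08, against the decreases of lhx5 and her3.

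Of 10 enveloping layer genes, which mark the outer epithelium of the embryo, 8 were higher and none lower, with cldnf at 1.40 ± 0.09 and klf17 at 1.12 ± 0.07 (list adjusted p = 0.0863). Of 16 cell cycle genes 2 were higher and 7 lower, including tyms at -0.55 ± 0.07 (list adjusted p = 0.0863). Non-neural ectoderm genes were 8 higher and 2 lower of 18, or 9 and 2 adjusted over the list alone, with gata3 at 2.14 ± 0.15 (adjusted p = 0.695). Ventral BMP genes were 7 higher and 3 lower of 17, with cdx4 at 1.96 ± 0.22 (adjusted p = 0.981). Adhesion and gastrulation movement genes were 10 higher and 4 lower of 25, or 11 and 4 adjusted over the list alone, with prickle1b at 1.99 ± 0.21 and wnt5b at 1.78 ± 0.09 (adjusted p = 0.695). Immediate early genes were 7 higher and 2 lower of 16, with dusp2 at 1.2 ± 0.10 (adjusted p = 0.695). Yolk syncytial layer genes were 4 higher and 2 lower of 11, with mttp at 1.66 ± 0.14 (adjusted p = 1), and germ plasm genes 2 higher and 2 lower of 5 (adjusted p = 1). Of 10 p53 target genes 3 were lower and none higher (adjusted p = 0.53), of 11 heat shock and chaperone genes 1 was higher and 2 lower (adjusted p = 0.902), and none of 7 ribosomal protein genes passed (adjusted p = 1). Except where stated, counts adjusted over the list alone were the same. The foxh1 transcript itself was at -0.51 ± 0.07 (adjusted p = 0.00422).

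Over all probes, 16454 of 32687 passed the test, 8259 higher and 8195 lower in mesendoderm precursors. A change of at least 2-fold was present in 2470 of these, 2333 higher and 137 lower. Other background corrections and normalizations, with the deposited ratios, gave 1698 to 2771 higher and 37 to 240 lower. Across 1 probe per gene, 801 of 2329 named genes were higher and 472 lower. Without replicate 3 or replicate 7 the count was 8485 or 8493, and each camera call was lost with an estimated correlation.

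Among genes with a symbol, mttp had the largest decrease in green sorted cells against whole embryos, and the Hairy-related gene her2 the largest increase. The lipid transfer gene mttp, on the yolk syncytial layer list, was at -6.39 ± 0.13 (SE, n = 5 arrays, limma adjusted p = 0.000341). For genes with 5 arrays the ratio averages all of them, but in each pairing the partner of the missing array did not enter the SE or p. The ectodermal regulators tfap2a and gata3 were at -2.62 ± 0.09 and -2.48 ± 0.12. In the other direction, her2 was at 5.35 ± 0.15 (n = 5 arrays, adjusted p = 0.000446), her4.5 at 3.78 ± 0.17, her9 at 3.48 ± 0.35 and her4.1 at 3.47 ± 0.26. The comparison served as a control for dissociation and sorting.

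The other large decreases were camsap2a (-4.34), the lipid transporter gene spns2 (-3.58), rbm47 (-3.35), the solute carrier genes slc14a2 (-3.27) and slc26a1 (-3.0), znf185 (-3.13) and the proton channel gene otop1 (-2.89). The other large increases were mat2al (3.26), the heme oxygenase gene hmox1a (2.37), foxo3b (2.34), the tyrosine aminotransferase gene tat (1.96), the caspase gene casp8 (1.90) and mespaa (1.82). By the rule that named them, each of these 20 genes had the same sign on every array that measured it.

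**Figure D2:**
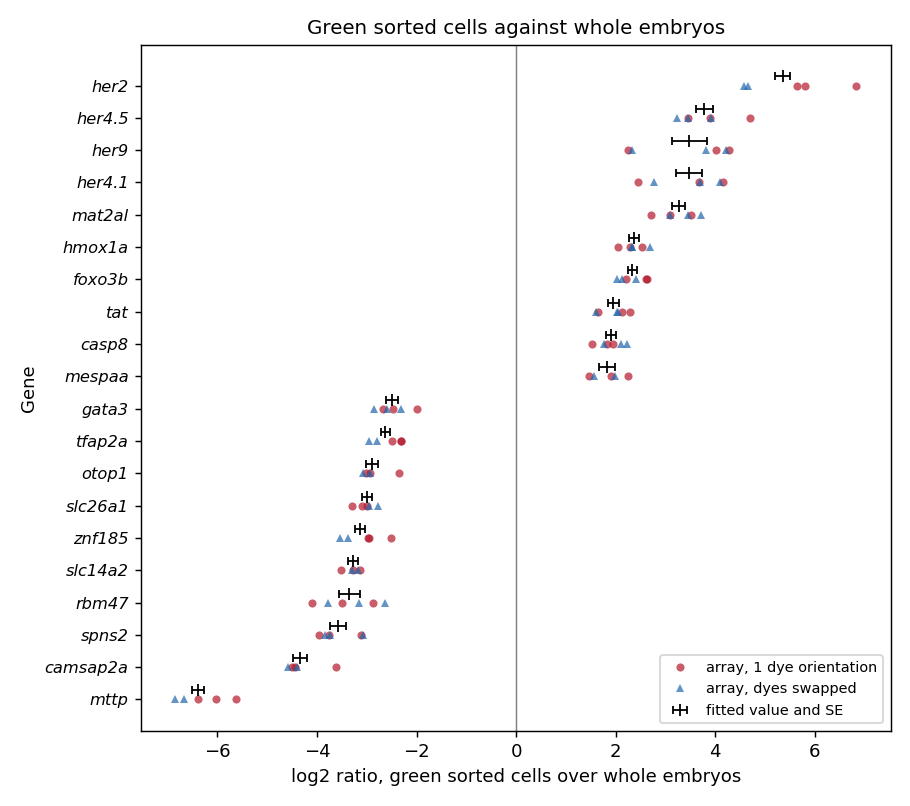
Log2 ratio of green sorted cells over whole embryos (horizontal axis) for the 10 named genes with the largest increases and the 10 with the largest decreases (vertical axis). Circles and triangles are single arrays of opposite dye orientation, n = 5 or 6 per gene, and black bars are the fitted value with its SE. The values ran from -6.39 for mttp to 5.35 for her2.

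Enveloping layer genes fell as a group: 8 of 10 were lower, 1 was higher and 1 did not pass, the same adjusted over the list alone, with a median log2 ratio of -1.39. Examples were klf17 at -1.81 ± 0.12, the claudin genes cldnf and cldne at -1.48 ± 0.08 and -1.44 ± 0.10, and the keratin gene krt5 at -1.47 ± 0.10, another probe of which passed in the opposite direction at 0.38. The list had a camera adjusted p = 0.0304, and an adjusted p = 0.838 with an estimated correlation. It missed the threshold whenever any of the 6 arrays was left out, and without replicates 5 and 6 its median was -1.36 and its adjusted p 0.0668 (0.0234 to 0.184 over alternatives with a preset correlation). Proteasome genes rose, with 9 of 13 higher, 1 lower and 3 not passing, or 10 higher and 1 lower adjusted over the list alone, and a median of 0.34. In that list psmb6 was at 1.01 ± 0.08, psmb9a at 0.68 ± 0.08 and psmb5 at 0.57 ± 0.09 (camera adjusted p = 0.0304; adjusted p = 0.838 with an estimated correlation; adjusted p = 0.0668 without replicates 5 and 6, and 0.0234 to 0.0669 over alternatives with a preset correlation).

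Yolk syncytial layer genes were 6 lower and 1 higher of 11, with mttp, slc26a1, gata6 (-1.73 ± 0.13) and hnf1ba (-0.62 ± 0.08) among the decreases. Their median was -0.47 and the list missed the threshold (camera adjusted p = 0.463). Of 18 non-neural ectoderm genes 9 were lower and 2 higher, including cdh1, which encodes E-cadherin, at -1.15 ± 0.16 (list adjusted p = 0.0969). Of 10 p53 target genes 5 were higher and 1 lower, including mdm2 at 1.03 ± 0.08 (list adjusted p = 0.225). Stress lists went both ways. Of 16 immediate early genes 3 were higher and 5 lower, with cebpb at -1.82 ± 0.08 and egr2a at -1.59 ± 0.08 (list adjusted p = 0.908), and of 11 heat shock and chaperone genes 2 were higher and 4 lower, with hsp70.3 at -1.29 ± 0.15 and hspe1 at 1.03 ± 0.07 (list adjusted p = 1).

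Endoderm genes were 2 higher and 6 lower of 11, with sox32 at -2.04 ± 0.24 and foxa2 at 1.68 ± 0.19 (list adjusted p = 0.521). Margin and mesendoderm genes were 5 higher and 9 lower of 28 (adjusted p = 1), dorsal organizer genes 7 higher and 5 lower of 24, or 8 and 6 adjusted over the list alone (adjusted p = 0.463), and neurectoderm genes 10 higher and 6 lower of 36, with sox11a at -1.26 ± 0.16 (adjusted p = 0.533). Nodal pathway components were 2 higher and 7 lower of 15, or 2 and 8 adjusted over the list alone, with eomesa at -1.01 ± 0.07 (adjusted p = 0.371). Germ plasm genes were 1 higher and 2 lower of 5, or 1 and 3 adjusted over the list alone, with dazl at -1.48 ± 0.07 (adjusted p = 0.521). Ventral BMP genes were 4 higher and 6 lower of 17, or 4 and 7 adjusted over the list alone, with vent at -1.06 ± 0.08 (adjusted p = 0.533). Wnt responsive genes were 2 higher and 4 lower of 12 (adjusted p = 0.521), FGF feedback genes 3 higher and 1 lower of 8, with etv4 at 1.04 ± 0.09 (adjusted p = 0.945), and retinoic acid genes 2 higher and 4 lower of 11, or 3 and 4 adjusted over the list alone (adjusted p = 1). Cell cycle genes were 3 higher and 5 lower of 16, or 2 and 5 adjusted over the list alone (adjusted p = 1), adhesion and gastrulation movement genes 3 higher and 5 lower of 24, with has2 at -1.33 ± 0.09 (adjusted p = 1), and ribosomal protein genes 2 higher and none lower of 7 (adjusted p = 0.516). Where no second count is given, the counts adjusted over the list alone were the same.

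In all, 13855 of 32169 probes passed the test, 6779 higher and 7076 lower in green cells, of which 396 were at least 2-fold higher and 1264 at least 2-fold lower (188 to 598 and 690 to 1858 with other background corrections and normalizations or the deposited ratios). Of 2316 named genes 504 were higher and 620 lower. The foxh1 transcript was at -0.00 ± 0.07 (limma adjusted p = 0.983), but at 0.27 with a passing test under median centring and in the authors' deposited ratios, and another probe of it passed at 0.38. The array of replicate 6 was read only in part, and with only the printed blocks complete there 8381 of 19778 probes passed, while without replicate 1, 2, 3, 4 or 5 the counts were 4112, 4190, 4117, 4059 and 7998.

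Red and green sorted cells differed by less. The clock and light response gene cry1a differed by 1.22 ± 0.12 on the log2 scale and rdh10a by 1.08 ± 0.10 (SE, n = 6 arrays in 3 dye-swap pairs, limma adjusted p = 0.0182 for both). No other gene with a symbol that passed with the same sign on every array differed by more than 0.68. The direction of this comparison was not settled. In the other comparisons the channel that the layout gives as Cy3 had the higher local background on every array, but here it did so on 0 of the 6 arrays, so sizes are given without saying which cells were higher. The comparison served as a control for photoconversion.

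On the side of cry1a and rdh10a lay pcf11, with a size of 0.68, asph, snx12 and znf592, each 0.67, znf644a (0.64), the splicing factor gene sfpq (0.63), mgaa (0.63) and plekha8 (0.61). On the opposite side lay nme2b.2 (0.59), the egg coat gene zp2.2 (0.53), hoxc13b (0.52), sacm1lb (0.51), tle3b and bhmt (0.48 each), abhd17aa, serpinb1l3 and sap30l (0.46 each) and ndufaf3 (0.44). By the rule that named them, each of these 20 genes had the same sign on all 6 arrays in the order of the files. Across all probes the arrays in that order correlated at 0.63 to 0.73 within a dye orientation, but at -0.266 to -0.084 between orientations.

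Proteasome genes were the only list that passed, with a median of size 0.13. Of 13 members 4 passed the test, or 6 adjusted over the list alone: psmb6, psmb5 and psma6l differed one way, by 0.42 ± 0.07, 0.35 ± 0.08 and 0.32 ± 0.07, and psmd11b the opposite way, by 0.39 ± 0.10. The list had a camera adjusted p = 0.043, and an adjusted p = 1 with an estimated correlation. It missed the threshold whenever any of the 6 arrays was left out. Of the remaining lists, dorsal organizer and p53 target genes had adjusted p = 0.551 each, neurectoderm genes 0.613, and immediate early, retinoic acid and ribosomal protein genes 0.594 each. The adjusted p was 1 for the margin and mesendoderm, endoderm, FGF feedback, Wnt responsive, ventral BMP, non-neural ectoderm, enveloping layer, yolk syncytial layer, germ plasm, heat shock and chaperone, cell cycle, Nodal pathway, and adhesion and gastrulation movement lists. Members that passed in these lists included the Wnt target gene axin2 (size 0.45 ± 0.07), the adhesion gene cdh1 (0.48 ± 0.08), ccnd1, which encodes cyclin D1 (0.43 ± 0.07), and sox11a (0.55 ± 0.08). In the p53 target list no member passed by its brightest probe, and casp8 had a size of 0.25 ± 0.07 (adjusted p = 0.0551). The brightest probe of foxo3b, also on that list, had a size of 0.31 (limma adjusted p = 0.0649). Another probe of foxo3b passed on the opposite side, with a size of 0.48 (limma adjusted p = 0.0198). The size for foxh1 was 0.21 ± 0.07 (adjusted p = 0.0866).

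In all, 4113 of 31524 probes passed the test, but only 14 of these differed at least 2-fold, and 322 of 2279 named genes passed. The median size among passing probes was 0.37. No probe passed after plain background subtraction or in the authors' deposited ratios, and without replicate 3, 4 or 6 the counts were 1, 1 and 0.

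The foxh1 transcript had a log2 ratio of 0.01 ± 0.09 in FoxH1 over control morphants (SE, n = 3 arrays, limma adjusted p = 0.944), and the sign of this ratio changed between settings. In simulated data this design found 0% of changes of 2 on the log2 scale, so a gene that did not pass is not shown to be unchanged. How this morpholino acts is not given in the sources used here. No single gene passed the test, so the values that follow are sizes, but this depended on the setting. Without background correction 6121 probes passed, with print-tip loess 415 and with spots of quality 0 left out 1599. Low ratios among members of the fixed lists included those of the BMP signal transducer gene smad1 (-2.46 ± 0.09), the mesodermal T-box genes tbx6 (-2.17 ± 0.16) and tbxta (-1.59 ± 0.14), the keratin genes krt5 (-1.94 ± 0.09) and krt4 (-1.59 ± 0.09), and sox32 (-1.52 ± 0.12), each with adjusted p = 0.103. High ones included those of the germ plasm gene dazl (2.12 ± 0.19), klf2a (1.56 ± 0.13) and the midbrain and hindbrain gene her5 (1.38 ± 0.13), also with adjusted p = 0.103. All of these had the same sign on 3 of 3 arrays, and all passed, at smaller sizes, without background correction. With the array of swapped dyes turned the other way, which exchanges the FoxH1 and dye terms of the fit, smad1, tbx6, tbxta, krt4, dazl and her5 changed sign, to 0.13, 0.35, 0.01, 0.34, -0.39 and -0.45. FoxH1 is a transcription factor of Nodal signalling.

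**Figure D3:**
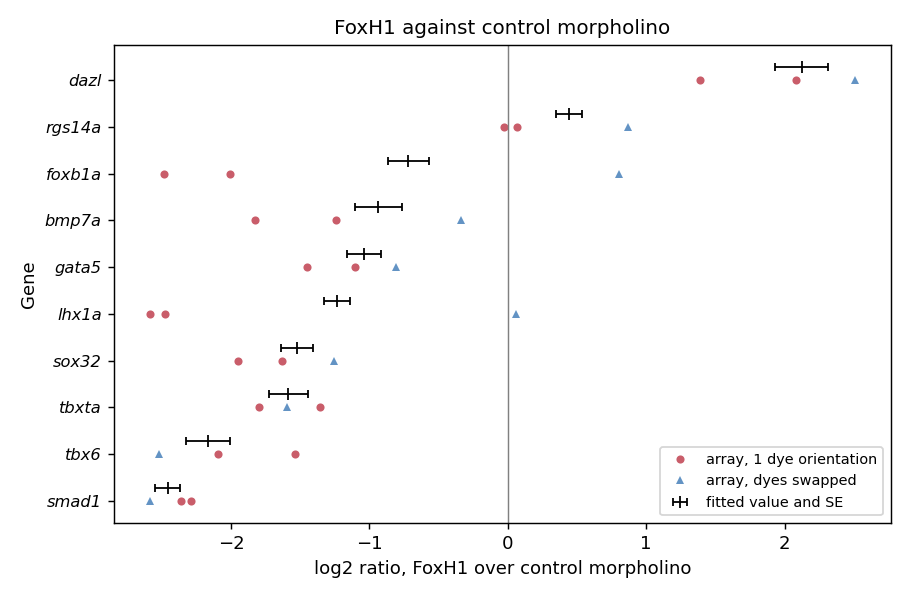
Log2 ratio of FoxH1 over control morphants (horizontal axis) for genes named from the margin and mesendoderm, endoderm, dorsal organizer, ventral BMP and germ plasm lists (vertical axis). Circles and triangles are single arrays of opposite dye orientation, n = 3 per gene, and black bars are the fitted value with its SE. None passed the test, and lhx1a, foxb1a and rgs14a had arrays on both sides of 0.

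Mesodermal and endodermal lists shifted lower in FoxH1 morphants. Margin and mesendoderm genes had a median of -0.37 over 27 members, none of which passed over all probes, while 12 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000467; adjusted p = 0.738 with an estimated correlation). Endoderm genes had a median of -0.57 over 11 members, 7 of them lower adjusted over the list alone, with gata5 at -1.04 ± 0.12 (camera adjusted p = 0.00434; adjusted p = 0.738 with an estimated correlation). Dorsal organizer genes had a median of -0.28 over 24 members, 2 of them lower adjusted over the list alone, with lhx1a at -1.24 ± 0.09 on the fit but of 1 sign on only 2 of 3 arrays (camera adjusted p = 0.000467; adjusted p = 0.738 with an estimated correlation). Ventral BMP genes had a median of -0.31 over 16 members, 6 lower adjusted over the list alone, with bmp7a at -0.94 ± 0.17 (camera adjusted p = 0.00434; adjusted p = 0.738 with an estimated correlation). Yolk syncytial layer genes, with 1 of 11 lower adjusted over the list alone and mttp at -1.42 ± 0.09, had a median of -0.31 (camera adjusted p = 0.00565; adjusted p = 0.738 with an estimated correlation). Ribosomal protein genes, with 1 of 7 lower adjusted over the list alone, had a median of -0.29 (camera adjusted p = 0.0404; adjusted p = 0.738 with an estimated correlation). Germ plasm genes had a median of 0.41, with 4 of 5 higher adjusted over the list alone (camera adjusted p = 0.0161; adjusted p = 0.738 with an estimated correlation). Without the array of swapped dyes the germ plasm median was 0.02 (adjusted p = 0.621), and no list passed. The 2 arrays left share 1 dye orientation, so values without that array mix the dye effect with that of FoxH1. The sizes depended on the setting: without background correction all 7 lists passed with smaller medians, from -0.47 for endoderm genes to 0.25 for germ plasm genes, and without the array of swapped dyes ventral BMP genes were at -0.74 (adjusted p = 0.0796).

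The remaining lists did not pass. FGF feedback genes had a median of -0.26 over 8 members, with 3 lower adjusted over the list alone and flrt3 at -1.31 ± 0.09 (adjusted p = 0.0847), and adhesion and gastrulation movement genes one of -0.11 over 24, none passing alone (adjusted p = 0.0724). Adjusted over the list alone, enveloping layer genes were 1 higher and 4 lower of 9 (adjusted p = 0.33), neurectoderm genes 5 higher and 2 lower of 35, with otx1 at 1.16 ± 0.14 (adjusted p = 0.552), non-neural ectoderm genes 1 and 1 of 17 (adjusted p = 0.552), and Wnt responsive genes 1 and 4 of 12, with lef1 at 1.06 ± 0.17 (adjusted p = 0.841). Cell cycle genes were 2 higher of 16, with ccna1 at 1.21 ± 0.09 (adjusted p = 0.243), Nodal pathway components 3 higher and 2 lower of 15 (adjusted p = 0.864), immediate early genes 2 higher of 15 (adjusted p = 0.552), retinoic acid genes 1 and 1 of 9, with aldh1a2 at -1.08 ± 0.14 (adjusted p = 0.94), and proteasome genes 1 and 1 of 13 (adjusted p = 0.94), all adjusted over the list alone. Neither heat shock and chaperone genes (adjusted p = 0.243, 10 measured) nor p53 target genes (adjusted p = 0.525, 10 measured) held a member that passed alone.

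No probe passed among 31493 tested, with a smallest limma adjusted p = 0.103, while 7756 lay at an unadjusted p under 0.05. The array with swapped dyes, in the sample order of the files, correlated at -0.37 and -0.51 with the other 2 arrays, which correlated at 0.83 with each other (across probes). With that array turned the other way 5740 probes and 0 lists passed, which by construction are the counts for the dye term of the fit. Whether the label of that array is right was not settled. If only the order of its 2 channels is wrong, the FoxH1 values given here are those of the dye and the turned ones those of FoxH1. If instead its samples were not swapped, all 3 arrays share 1 dye orientation, and neither fit parts FoxH1 from the dye. Local background on that array was higher in the channel labelled Cy3 (336.6 against 309.7), as on the other 2 arrays. Without it 9176 probes and 0 lists passed, but the 2 arrays left share 1 dye orientation, so these counts hold the FoxH1 and dye effects together. Across probes the dye effect had an SD of 0.636, against 0.387 for the FoxH1 effect.

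**Figure D4:**
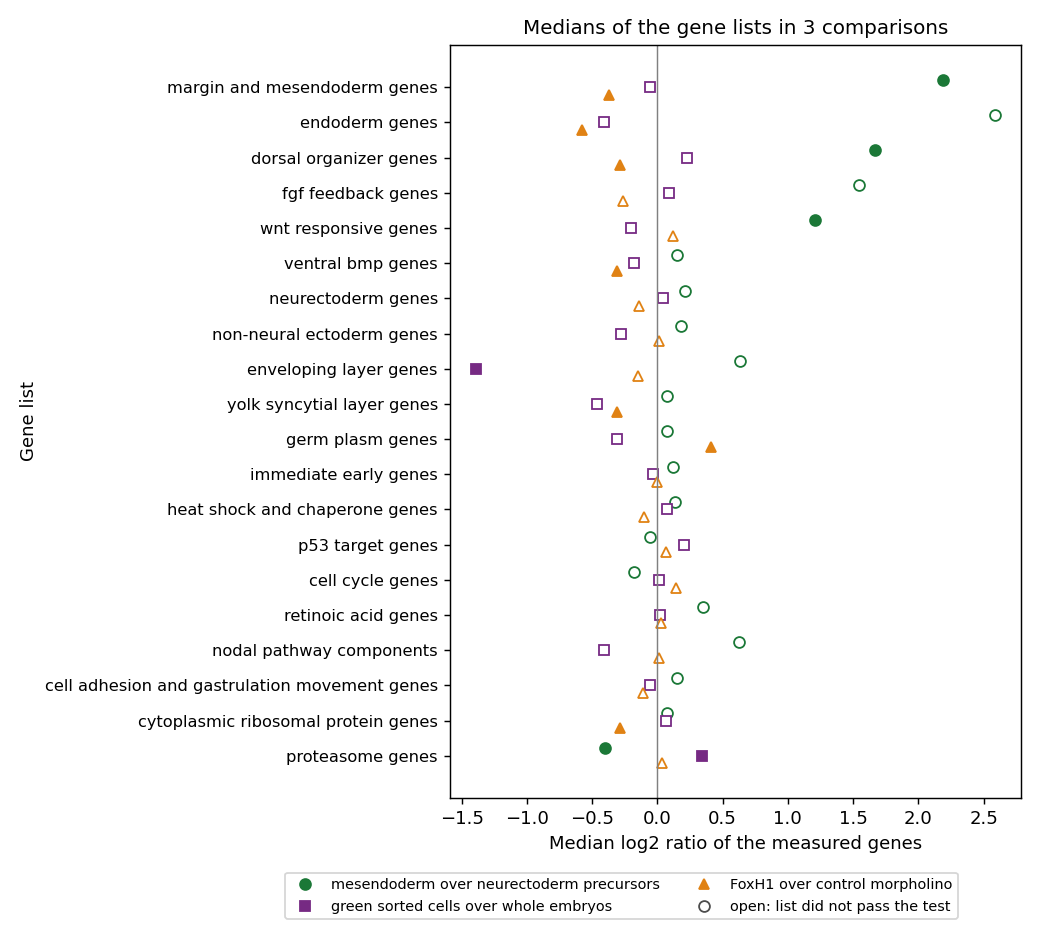
Median log2 ratio of the measured genes (horizontal axis) of 20 gene lists (vertical axis) in the mesendoderm, green cell and FoxH1 comparisons. Filled symbols are lists that passed the camera test with a preset correlation and open symbols those that did not. The medians ran from -1.39 for enveloping layer genes in green cells to 2.59 for endoderm genes in mesendoderm precursors.

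Genes higher in mesendoderm precursors were set against the FoxH1 ratios, since FoxH1 acts in Nodal signalling and the comparisons share no array. The 757 genes with a symbol that were higher in mesendoderm precursors had a median FoxH1 ratio of -0.02 (limma camera across genes, n = 757 genes from 3 arrays, p = 0.103), and the 456 that were higher in neurectoderm precursors one of 0.02 (n = 456 genes, p = 0.258). Among the 252 genes at least 2-fold higher in mesendoderm precursors, the median was -0.10 and 151 (59.9%) had a ratio below 0 (limma camera, n = 252 genes from 3 arrays, p = 0.00175). Of the genes that did not pass as higher in mesendoderm precursors at any size, 47.4% had a ratio below 0. With an estimated correlation neither the 2-fold set (limma camera, n = 252 genes, p = 0.112) nor the larger set (n = 757 genes, p = 0.289) passed. Without the members of the fixed margin and mesendoderm list the 2-fold set was at -0.10 (limma camera, n = 234 genes, p = 0.00599) and the larger set at -0.01 (n = 734 genes, p = 0.199). With the array of swapped dyes turned the other way, the medians were -0.19 and -0.18, and that of genes higher in neurectoderm precursors was -0.10. That would be the right fit only if the order of the channels of that array is wrong. Across 2193 genes, which are not independent replicates, Spearman's rho between the ratios was -0.10 and Pearson's r -0.17.

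Probes that passed in the mesendoderm comparison often passed in the sorting control with the opposite sign. Of 32141 probes tested in both, 8434 passed in both, and 7403 of these (87.8%) had opposite signs. Independent lists would share 1808 probes higher in mesendoderm precursors and lower in green cells, where 3820 were found, and 1716 the other way around, where 3583 were found. Only 366 were higher and 665 lower in both, where independent lists would share 1731 and 1792 (Fisher's exact test, largest p of the 4 = 2.3e-310). The test takes probes as independent, which they are not, so this p does not measure the spread between arrays. Of 2468 probes at least 2-fold changed between precursors, 1671 (67.7%) passed in the sorting control. Among genes named in both, sox32, gata6, gata3, klf17, cldnf and mttp were higher in mesendoderm precursors and lower in green cells, and her4.1 and her4.5 were lower and higher. In contrast, aldh1a2, cdx4, id3 and wnt5b were higher in both, and so were foxa2 and mespaa.

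Of 31506 probes tested in both the mesendoderm and the photoconversion comparison, 3392 passed in both, and the sizes of the ratios went together with an absolute Pearson's r of 0.61 across probes, which are not independent. With the arrays as ordered in the files 51 of these (1.5%) had opposite signs, and with the sign turned all others would (Fisher's exact test, largest p of the 4 = 1.6e-219). The sorting and photoconversion controls both held RNA of green cells, taken as shared in the simulation though no label pairs their arrays. The correlation between these controls was -0.58 in the order of the files, against -0.375 simulated for unchanged groups that share green RNA. The covariance was -0.0601 against a simulated -0.00276, a difference of -0.0573, and 3245 probes passed in both. The 20 simulations gave 0 such probes, but they held no changed probe. Their 0 was therefore set in advance and does not show what shared RNA adds to this overlap. Both correlations with the photoconversion comparison and the covariance hold for the direction as labelled. If it is turned they take the opposite sign while the simulated values do not, so the difference from simulation would change in size and sign.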

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

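The tests of the 2 arrays that stood apart, of cell loss and of stress were chosen after the result was seen, and so were the split tests of the mesendoderm comparison. Single arrays lay far from the others of their group for 6 of 209 named genes, 0 of 60 list medians and 1 of 16 array quantities. Chance gives about 1 in 20 groups, so the genes as a group are not more than chance gives. In the mesendoderm comparison this was cldnb on replicate 1 (0.57, others 0.86 to 1.07). In green cells against whole embryos they were, on replicate 5, camsap2a (-3.61, others -4.59 to -4.40), otop1 (-2.36, others -3.08 to -2.94) and cdx4 (1.97, others 0.57 to 0.93), foxn4 on replicate 4 (1.15, others 0.83 to 0.93) and dazl on replicate 2 (-1.37, others -1.52 to -1.47). The file of replicate 6 held 22147 spots against 36288 in the others.

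Large decreases in green cells against whole embryos were more frequent than large increases, with 1264 probes against 396. Replicates 5 and 6 were not the source, since 1444 probes were at least 2-fold lower without them, 1208 of which were also lower with all arrays. Loss of enveloping layer and yolk syncytial cells in dissociation or sorting may contribute. Of the measured members of their lists 80% and 54.5% were lower. The share was 28.1% among members of 6 other embryonic lists, while 620 of all 2316 named genes were lower. The rule asked for a lower share in those 6 lists than that of all named genes, so the test could not decide. A stress response was not decided, since the higher of the medians of the immediate early and heat shock lists was 0.076 while their members went both ways. This test was first read as excluding stress, was set aside after its value was seen, and was restored with a rule reworded so that members going both ways decide nothing. The difference between sorted cells and whole embryos itself stays open, untested.

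Among the 35 splits of the mesendoderm arrays into orientation groups of equal size, 1 gave as many probes, the real one (16454, highest other 0), and 2 gave as many lists (4 real, highest other 5). The arrays go together in 4 dye-swap pairs, and only 8 of the splits part every pair, which is too few for a share under 0.05: 1 of the 8 gave as many probes (highest other 0) and 1 as many lists (highest other 3). The pairs were found in the data, and the wording of these split predictions was changed after the splits had been run. The 10 splits of each control are too few for a share under 0.05: for green cells 1 split gave as many probes (13855, highest other 0) and 1 as many lists (2, highest other 0), and for red against green cells 1 gave as many probes (4113, highest other 0) and 3 as many lists (1, highest other 2). All splits but the real one turn the ratios of some arrays. An effect present on every array then cancels in part and adds to the spread. Their probe counts of 0 therefore do not show what chance would give.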

How the results depend on the processing

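Tests with complete printed blocks, with replicates 5 and 6 left out, with the swapped FoxH1 array turned the other way or left out for the 2-fold set, with the 2-fold set under an estimated correlation or without the margin list, with repeated source plates left out or their names kept, and with swaps paired by their deviations were chosen after the result was seen. Where no cause is named, the cause was not tested.

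Every one of the 72, 78 and 45 genes named as changed in the mesendoderm, green cell and red cell comparisons kept its direction in each alternative that gave it a value. For genes chosen for the same sign on every array, leaving an array out could not turn it. Of the 72, 78 and 45 genes, 69, 70 and 0 also stayed on the same side of the threshold with all arrays. With arrays left out 58, 71 and 0 did so, and there 30 of 79 green cell genes had a value only without replicate 6, since they were missing from its file. All 4 mesendoderm lists stayed past the threshold with any array left out.

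An adjusted p under 0.01 gave 7520, 7713 and 0 probes for mesendoderm, green and red cells and an overlap of 2498 between the mesendoderm and sorting comparisons, and a 2-fold change gave 2470, 1660 and 14. Both are stricter by construction. With an estimated correlation 0 lists passed in each of the 4 comparisons, and with limma's fry test 16, 7, 0 and 2. Averaging the probes of a gene gave 7 mesendoderm and 0 red cell lists. Arrays taken as independent gave 8381 red cell probes and an overlap of 13391, and the pairing with the most calls gave 8710 red cell probes. No red cell list passed without background correction, with print-tip loess or with all plate names kept, and no red cell probe after plain subtraction or in the deposited ratios (limma, 9263 at an unadjusted p under 0.05 as reported). Median centring gave 4 green cell lists. FoxH1 probes numbered 6121 without background correction, 415 with print-tip loess and 1599 with spots of quality 0 left out. Named FoxH1 genes passed in the reported direction in 73 of 383 results over settings with all arrays, and in the opposite direction in 2. Without background correction the FoxH1 medians of the margin, organizer, ventral BMP, yolk and germ plasm lists shrank to -0.177, -0.155, -0.161, -0.179 and 0.249, and without replicate 3 those of ventral BMP and germ plasm genes were -0.744 and 0.019. Green cells gave 8381 probes with complete blocks, where fewer probes were tested, and 0 lists without replicates 5 and 6.

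The median FoxH1 ratio of genes higher in mesendoderm precursors was -0.101 for those at least 2-fold higher, -0.071 without a dye term and -0.187 to -0.011 with each array left out, lowest without replicate 3. The 2-fold set was at -0.099 without the margin list, and with an estimated correlation neither set passed. Without replicate 3, the swapped array, the arrays left share 1 dye orientation, and without a dye term the orientations are unequal, so these values mix the dye effect with that of FoxH1. The same holds for the -0.304 of the 2-fold set with the swapped array left out. With the swapped array turned the other way, which exchanges the FoxH1 and dye terms, the medians were -0.178, and -0.194 for the 2-fold set, genes higher in neurectoderm precursors were also lower, at -0.10 and -0.335, and 5740 probes and 0 lists passed. With the swapped array turned the other way germ plasm genes were at -0.388, lef1 at -1.001 and hspe1 at 1.33, all reversed, and hspe1 was also reversed without replicate 3, at 0.93 (-0.426 to 0.93 with each array left out). The foxh1 ratio in green cells became 0.272 with median centring and 0.271 in the deposited ratios.

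With each array left out in turn, probes numbered 8485 to 13211 for mesendoderm, 4059 to 13192 for green cells, where leaving out replicates 1 to 5 left fewer probes to test, 0 to 1752 for red cells and 0 to 9176 for FoxH1. Lists numbered 0 to 3 for green cells, 0 to 0 for red cells and 0 to 7 for FoxH1. The adjusted p of the enveloping layer list in green cells was 0.0234 to 0.184 over its alternatives with a preset correlation, that of the proteasome list there 0.0234 to 0.0669, and that of the red cell proteasome list 0.0288 to 0.245.

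No paired analysis was possible because each comparison is made within an array and nothing in the labels pairs arrays across comparisons. Not run were the foreground median, which the files do not hold, and a block for slide or scan, which the headers do not give. The brightness filter removed no tested probe, so leaving it out says nothing. Signal over background limits what dim spots can show, and in the FoxH1 comparison 83.5% to 95.5% of spots were above background.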

Other observations

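The same-oligo test of the plates was chosen after the result was seen. The retinoic acid synthesis gene aldh1a2 was higher in mesendoderm precursors (2.99) and in green cells (1.35), while rdh10a was higher in mesendoderm precursors (3.73), lower in green cells (-1.74) and among the genes that differed most between red and green cells, with a size of 1.08. The mesodermal gene mespaa was higher in both, at 3.04 and 1.82, and her2 and her9, which rose in green cells, did not pass the test in mesendoderm precursors (-0.05 and -0.22). Probes without a symbol, chosen after their values were seen, included those titled mix-type homeobox gene 1 and gene 2, at -5.79 and -3.69 in green cells. Probes with mtx1 in the title were at -5.04 and -4.04 there, and a probe titled mtx2 was at -3.61.

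The ratios of the mesendoderm comparison followed those of both sorting controls across probes. A common dye bias as the only source is argued against, since the correlation kept its sign in every combination of forward and swap arrays. Its size depended on the combination, so a part of it from the dyes is not excluded. For green cells it was -0.304 and -0.302 between like orientations, against -0.523 and -0.535 between unlike ones. For red cells, by their labels, it was 0.159 and 0.126 against 0.536 and 0.571. Probe brightness is argued against as well, since within 10 classes of brightness the median correlation was -0.472 and 0.609. Handling that differed between the 2 sorted samples may contribute, since over probes that did not pass in the mesendoderm comparison the correlation was -0.273 (15784 probes) and 0.392 (15331 probes). A shared biological difference between the samples would give the same values, and the rule for reading this test was set after they were seen. The sign for red cells rests on an unsettled direction.

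In the mesendoderm comparison 4 source plates gave nearly the same ratios well by well (r at least 0.973), in green cells less so (0.939) and in red cells far less (0.45). Place on the slide or the printing pin is argued against, since the lowest r was still 0.97 after print-tip loess. The same oligos may have stood in the wells of these plates, since their brightness on the amplified arrays also went together, with a lowest r of 0.993, against at most 0.076 on the FoxH1 arrays. No biological explanation was tested.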
